A study of Mus musculus with 2 samples.

How the data were processed

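H3K27ac was mapped by ChIP-seq in stomach tissue pooled from male and female mouse embryos at embryonic day 14.5, with a library size range of 300 to 500 bp, per the labels. The series held 1 group of 2 samples that the labels number as biological replicates 1 and 2; each had its own pooled tissue sample. Both pools came from mice of 1 strain background, B6NTac;B6NCrl.

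The authors deposited 4 peak lists on the mm10 assembly, each in narrowPeak format without a header. Per the deposited descriptions of the files, 1 list was called on replicate 1 against 1 control file, 1 on replicate 2 against 2 control files, 1 on the pooled reads of both replicates against the same 2 control files, and 1 was a replicated set derived from the other 3 lists. The aligner, the peak caller, its thresholds and the rule behind the replicated set were not given in the sources used here. Each peak carried a signal value, which is the authors' deposited enrichment over the control for that peak and is called the enrichment value here. Each peak also carried the deposited −log10 p-value and −log10 q-value and the offset of its summit. All lists reached down to a −log10 p-value just above 2, so they included weak peaks. Every row of the replicated set was also a row of the pooled list, so its enrichment values are pooled values without a replicate error. Enrichment values were used to describe, rank or filter peaks within a list. They also served to compare promoter peaks between gene lists within the pooled values, and for the rank correlation between the replicates. No change between replicates was read from them, since lists of different lengths cannot show one. The lists hold no read counts: the depth of each library is unknown, and no interval that needs a depth is given. A difference in depth between the replicates, or in the control reads used for them, would change how many weak peaks passed the threshold.

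Chromosome names and lengths of the GRCm38.p6 genome, which is mm10, were checked against the largest peak ends. Peaks on the 19 autosomes and on X and Y were analysed, which left out 6 peaks of replicate 1, 10 of replicate 2, 7 pooled peaks and 5 replicated peaks on other contigs. Genes came from GENCODE M21, and 21853 protein-coding genes with a protein-coding transcript were used. Coordinates are 1-based. Analyses were run in Python 3.11 with numpy, pandas and scipy.

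Peaks of both replicates were compared by overlap of 1 bp or more. Chance overlap came from 1000 random placements of each peak on the sequenced bases of its own chromosome (permutation test, one-sided). Spearman's rho was computed over replicate 1 peaks that overlapped a replicate 2 peak, taking the strongest where there were several. Summits were assigned to within 1 kb of a transcription start site (TSS), an exon, an intron or the space between genes, in that order, and shares were set against 1000 placements (permutation test, two-sided). A gene was counted as having a promoter peak where a peak overlapped 1 kb either side of any of its TSSs. A distal peak was a peak whose summit lay over 1 kb from every TSS; it was assigned to the gene with the nearest TSS within 100 kb.

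The 20 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. List members all matched the annotation, 1 of them by an older symbol. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. It was also compared with 10000 random lists of the same size matched on the CpG observed/expected ratio. That ratio was taken 500 bp either side of the gene's annotated 5′ end, which need not be the TSS with the peak. Median counts of distal peaks were compared with 10000 random lists matched on the distance between the neighbouring genes' TSSs (permutation test, two-sided, smallest possible unadjusted p 0.0002). Genes are not replicates, so these tests describe these samples. Distal peaks within 12.5 kb of each other were stitched into domains and ranked by the sum of width times enrichment value. Domains past the point where the scaled rank curve reaches a slope of 1 were counted. For the comparison of lists between replicates, the strongest 47584 peaks of each by p were used, and genes with a promoter peak in 1 replicate only were tested by Fisher's exact test. The consensus sequences of 15 transcription factor families (among them TGTTTAC for FOX, GGAATGY for TEAD, ACAAAGG for SOX and CCWTWTWAGG for CArG) were searched in 500 bp windows around distal summits and in GC-matched windows 5 to 20 kb away that lay outside every peak list (Fisher's exact test, two-sided, adjusted over the motifs).

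The rule for named genes took 2 to 4 members of each list, those with the strongest promoter peak and, where members lacked a peak, those without one. Where more members lacked a peak than could be named, the first in the order of the list were taken, a choice made after the values were seen. The rule also took the genes nearest to the 20 highest-ranked domains and the genes of the 10 strongest replicated promoter peaks. Genes named outside that rule are identified as chosen after their values were seen.

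The scripts were tested on simulated data. In 60.0% of simulated peaks an overlap was found where 59.7% had been copied. At list sizes of 20 genes, 94% of lists planted at 90% against 50% were called and 3% of unplanted lists were. Distal lists planted at 3 times the count were all called, and 0% of unplanted ones. In the promoter scan all genes given a peak were found, and 5.56% of the other genes were counted through a peak placed at a neighbouring gene. All 50 planted peak clusters were stitched, and 0 of 14 unplanted motifs were called.

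Alternatives were a reciprocal overlap of 50%, only peaks with a −log10 q-value of 5 or more, equal numbers of peaks, a 2.5 kb TSS window, a 50 kb reach, 5 kb stitching, ranking by width alone, 300 bp motif windows, neighbours not matched on GC, and each replicate alone. Alternatives added after seeing the data were replicated peaks that overlap a peak of both replicates, peaks lying wholly outside the TSS windows, motif windows with at most 20% repeat-masked bases, and consensus sequences written backwards. The text files that describe the lists hold no measurements and were not analysed.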

Results

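H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of mouse embryos at embryonic day 14.5. At this age the stomach consists of an endodermal epithelium inside a mesenchyme that forms smooth muscle, with neural crest cells, vessels and an outer mesothelium. The design held 1 group of 2 biological replicates, each pooled from male and female embryos, so no condition was set against another. The comparisons were between the replicates, between groups of genes, and between peaks and the rest of the mm10 genome. Replicate 1 gave 47590 peaks and replicate 2 gave 106453, a 2.24-fold difference. The pooled reads gave 81946 peaks, of which 45610 made up the deposited replicated set, with a median width of 594 bp and a covered length of 38.1 Mb. The peak lists hold no read counts, so the depth behind each list is unknown and no interval that needs it is given. Enrichment values are the authors' values per peak; those given for genes are from the pooled reads and have no replicate error.

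The first comparison was how far the replicates gave the same acetylated regions. Of the replicate 1 peaks on placed chromosomes, 37233 of 47584 (78.2%) overlapped a replicate 2 peak, and 30653 of 106443 replicate 2 peaks (28.8%) overlapped a replicate 1 peak. Random placement gave 4.04% and 1.81% (one-sided permutation test, p = 0.001 for both, the smallest that 1000 placements can give). Placements were not held to gene starts, although 30.0% of replicate 1 and 18.5% of replicate 2 summits lay within 1 kb of one. The p-value therefore cannot separate agreement of these replicates from a shared preference for promoters. Where both peaks had to share at least 50% of their length, the shares were 30.6% and 13.7%, and with equal numbers of peaks they were 69.0% and 53.6%. Across the 37233 overlapping peaks, the enrichment values of the replicates had a Spearman's rho of 0.540. This correlation is across peaks, which are not independent replicates.

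The replicated set kept 55.7% of the pooled peaks, and it was the stronger part of them. Its median enrichment was 4.48, against 2.88 for the pooled peaks outside it. The set overlapped 78.6% of replicate 1 peaks and 43.8% of replicate 2 peaks. Seen from the set, 99.3% of its peaks overlapped a replicate 2 peak and 64.8% a replicate 1 peak. Only 29295 (64.2%) overlapped a peak of both deposited replicate lists, so the set also holds 16310 peaks seen in fewer lists, with a median enrichment of 3.72.

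Acetylated regions lay at gene starts far more often than random placement gave. Of the replicated peaks, 30.5% had their summit within 1 kb of a protein-coding transcription start site (TSS), 11.4 times the 2.67% of random placements, and 29.7% lay between genes, against 57.6% (two-sided permutation test, p = 0.002 for both, the smallest possible). Introns held 37.3% against 37.2% (permutation p = 0.603) and exons 2.54% against 2.55% (permutation p = 0.979). From replicate 2 alone the TSS share was 18.5%, 6.98 times that of random placements, and with the 2.5 kb window the share was 35.6% and the ratio 5.85. Over the replicates, the TSS share was 24.2% ± 8.11 and the share between genes 31.8% ± 2.38 (SD, n = 2). The intron and exon values lay on either side of chance when other peak sets were used. Replicate 2 alone had 45.0% of its peaks in introns, and replicated peaks overlapping both replicates had 32.4%.

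Of 21853 protein-coding genes, 11082 (50.7%) had a replicated peak within 1 kb of a TSS. The question was which cell types' genes were among them. Regulators of the gut mesenchyme had promoter peaks at 26 of 27 genes, and smooth muscle genes at 22 of 22. The mesenchymal share was 96.3% ± 0 and the smooth muscle share 100% ± 0 over the replicates (SD, n = 2). The strongest mesenchymal promoter peaks were at Meis1, a TALE homeodomain factor (11:19007053–19022317, enrichment 34.2), at Nr2f2, a nuclear receptor also called COUP-TFII (7:70354514–70361772, 33.5), and at its relative Nr2f1 (13:78197129–78200924, 31.4). Hand1, a bHLH factor, was the gene without a peak. Barx1, a homeodomain factor required in stomach mesenchyme, was named after its value was seen and had an enrichment of 18.0 (13:48657481–48662877). In smooth muscle the strongest were Srf, the serum response factor that drives contractile genes (17:46554490–46557603, 17.3), Smtn, encoding smoothelin (11:3535081–3536914, 16.9), and Tpm1, encoding a tropomyosin (9:67046589–67050312, 16.8). Both shares exceeded that of other protein-coding genes (two-sided Fisher's exact test, adjusted p = 3.19e-06 for each, over 20 lists).

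Epithelial genes were the next lists. Gut endoderm regulators had a promoter peak at 20 of 22 genes and epithelial junction and keratin genes at 23 of 25 (Fisher's exact test, adjusted p = 0.00031 and 5.74e-05). Over the replicates the shares were 90.9% ± 12.9 and 90% ± 2.83 (SD, n = 2). Klf4, a zinc finger factor of differentiating epithelia, had an enrichment of 15.3 (4:55532538–55534262), and Grhl2, a regulator of epithelial junctions, 14.2 (15:37232314–37234468). The endoderm genes without a replicated peak were Cdx2, a regulator of intestinal identity, and Trp63, encoding p63 of stratified epithelia. Both had a peak in replicate 2 and not in replicate 1, with enrichment values of 2.86 and 3.81. Among junction and keratin genes, Esrp2, an epithelial splicing factor, had 14.4 (8:106135275–106138216) and Epcam, an epithelial adhesion molecule, 13.2 (17:87635922–87636585). Marveld3, a tight junction gene, and Ap1m2, a sorting adaptor of epithelial cells, had no replicated peak; Marveld3 had one in replicate 1 (3.12).

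Signalling genes of the hedgehog, Bmp, Wnt and Fgf pathways had a promoter peak at 24 of 28 (85.7% ± 10.1 over the replicates, SD, n = 2; Fisher's exact test, adjusted p = 0.000412). The strongest were Smo, the hedgehog signal transducer (29.3), and Ptch1, the hedgehog receptor (27.7). Ptch1, Gli1, Bmp4, Wnt5a and Sfrp1 also stand on the mesenchyme list, and Shh and Ihh on the endoderm list. The signalling list is therefore not independent of these lists. Bmp2, a Bmp ligand, and Grem1, a Bmp antagonist, had no replicated peak. All 20 housekeeping genes had a peak (adjusted p = 7.86e-06, Fisher's exact test), led by Actb at 39.95 and Ywhaz at 39.9. Cell cycle genes had 19 of 22 (adjusted p = 0.00159, Fisher's exact test), with Birc5, encoding survivin, at 17.7 and the replication helicase gene Mcm4 at 14.8, and with no replicated peak at Mcm3 or Bub1. Bmp2 and Mcm3 had a peak in replicate 2. The cell cycle call was lost against random lists matched on promoter CpG content, which averaged 77.8% (permutation adjusted p = 0.509).

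Genes of vessels, nerves, blood and mesothelium gave mixed counts. Endothelial genes had 15 of 20 (Fisher's exact test, adjusted p = 0.0463), with Ets1, an endothelial transcription factor, at 13.7 and Eng, encoding endoglin, at 8.08, and with no replicated peak at Tie1 or Sox7. That call rested on replicate 2, in which 20 genes had a peak against 11 in replicate 1 (77.5% ± 31.8, SD, n = 2), and without replicate 2 the adjusted p was 0.534 (Fisher's exact test). It was also lost with stricter peaks (60%), with equal numbers of peaks (50%), among peaks overlapping both replicates (45.0%) and with the 2.5 kb window, where the share was again 75% (Fisher's exact test, adjusted p = 0.0534). Against CpG-matched lists, which averaged 46.8%, the call held (permutation adjusted p = 0.0168). With pooled peaks the endothelial share was 95% and passed (Fisher's exact test, adjusted p = 0.000382). Enteric nervous system genes had 9 of 24 (adjusted p = 0.224) and mesothelial genes 4 of 13 (adjusted p = 0.183, Fisher's exact test for both), neither different from other genes. Erbb3, a neuregulin receptor of neural crest and glia, had 18.8 and Hand2, a factor of enteric neurons and mesenchyme, 15.5, while Phox2a and Tlx2, homeobox genes of enteric neurons, had no replicated peak. Wt1 had 8.44 and Bnc1 3.84, while the uroplakin genes Upk3b and Upk1b had no replicated peak. Of these 4 genes, Tlx2 (5.08) and Upk3b (4.13) had a peak in replicate 2, and both and Upk1b had one in the pooled list. Over the replicates the shares were 47.9% ± 8.84 for enteric and 38.5% ± 32.6 for mesothelial genes (SD, n = 2). With pooled peaks they were 58.3% and 46.2%, against 55.8% and 55.9% of other genes (Fisher's exact test, adjusted p = 0.840 and 0.611). The mesothelial share passed as lower than that of other genes in replicate 1 alone (15.4%) and with stricter peaks (7.69%), and was 61.5% in replicate 2 alone. Blood and immune genes had 5 of 20 (adjusted p = 0.0309, Fisher's exact test), with Lcp1, encoding plastin 2, at 7.22 and the erythroid factor Klf1 at 6.14, and no peak in any list at Gata1 or the globin gene Hba-a1. Without replicate 1 the blood and immune share was 45.0% and the call was lost (Fisher's exact test, adjusted p = 0.297), as it was with pooled peaks (Fisher's exact test, adjusted p = 0.413); without replicate 2 the share was 15.0%.

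Genes of other organs, and genes of the mature stomach, had promoter peaks less often than other protein-coding genes. Brain regulators and neuronal genes had 2 of 29 (Fisher's exact test, adjusted p = 3.19e-06), which were Dlx1 at 6.33 and Dlx2 at 3.59; Neurod1 and Neurod2 had no replicated peak. Liver genes had 3 of 20 (Fisher's exact test, adjusted p = 0.00216), with Hhex at 6.14 and F2 at 4.22 and no replicated peak at Alb or Afp, the genes of albumin and alpha-fetoprotein. Pancreas genes had 4 of 20 (Fisher's exact test, adjusted p = 0.00998), with the islet factors Nkx6-1 at 6.52 and Insm1 at 4.79 and no replicated peak at Ptf1a or Cpa1. Intestine genes had 5 of 20 (Fisher's exact test, adjusted p = 0.0309), with Satb2 at 5.94 and Lgals4 at 4.35 and no replicated peak at Cdx1 or Fabp1. Skeletal muscle genes had 5 of 20 (Fisher's exact test, adjusted p = 0.0309), with Mylpf at 7.67 and Tnni2 at 6.11 and no replicated peak at Myod1 or Myf5. Mature gastric genes, which serve acid, mucus, hormone and digestive enzyme secretion in the adult, had 3 of 21 (19.05% ± 6.73 over the replicates, SD, n = 2; Fisher's exact test, adjusted p = 0.00147). They included the mucin gene Muc1 at 6.71 and Bhlha15, a factor of secretory cells, at 4.22, while the pepsinogen gene Pgc and the intrinsic factor gene Gif had no replicated peak. Among the genes named here without a replicated peak, Afp, Cpa1 and Cdx1 had one in replicate 2 (2.67, 4.396 and 3.81). Olfactory receptor genes, silent outside the nose, had 1 of 1134, which was Olfr187 at 4.22. Several of these shares moved with the replicate used. From replicate 1 and replicate 2 alone they were 3.45% and 10.3% for brain, 10% and 30.0% for liver, 10% and 40% for pancreas, 10% and 35.0% for intestine, and 14.3% and 23.8% for gastric genes, with 2 and 6 olfactory receptor genes. From replicate 2 alone the pancreas and intestine calls were lost (Fisher's exact test, adjusted p = 0.141 and 0.0842), and the pancreas call also with pooled peaks (35.0%, adjusted p = 0.0847). The skeletal muscle call was lost with the 2.5 kb window (30.0%), from replicate 1 (30.0%) or replicate 2 (35.0%) alone and among peaks overlapping both replicates (25%), with adjusted p from 0.0784 to 0.198 (Fisher's exact test). The low shares of gastric, liver, pancreas, skeletal muscle, intestine and blood genes were not distinguishable from random lists matched on promoter CpG content, which averaged 24.3%, 27.2%, 38.5%, 36.5%, 23.4% and 21.8%. The brain and olfactory lists stayed below such lists, which averaged 66.1% and 9.52% (permutation adjusted p = 0.0008 for both, at the smallest possible unadjusted p).

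**Figure D1:**
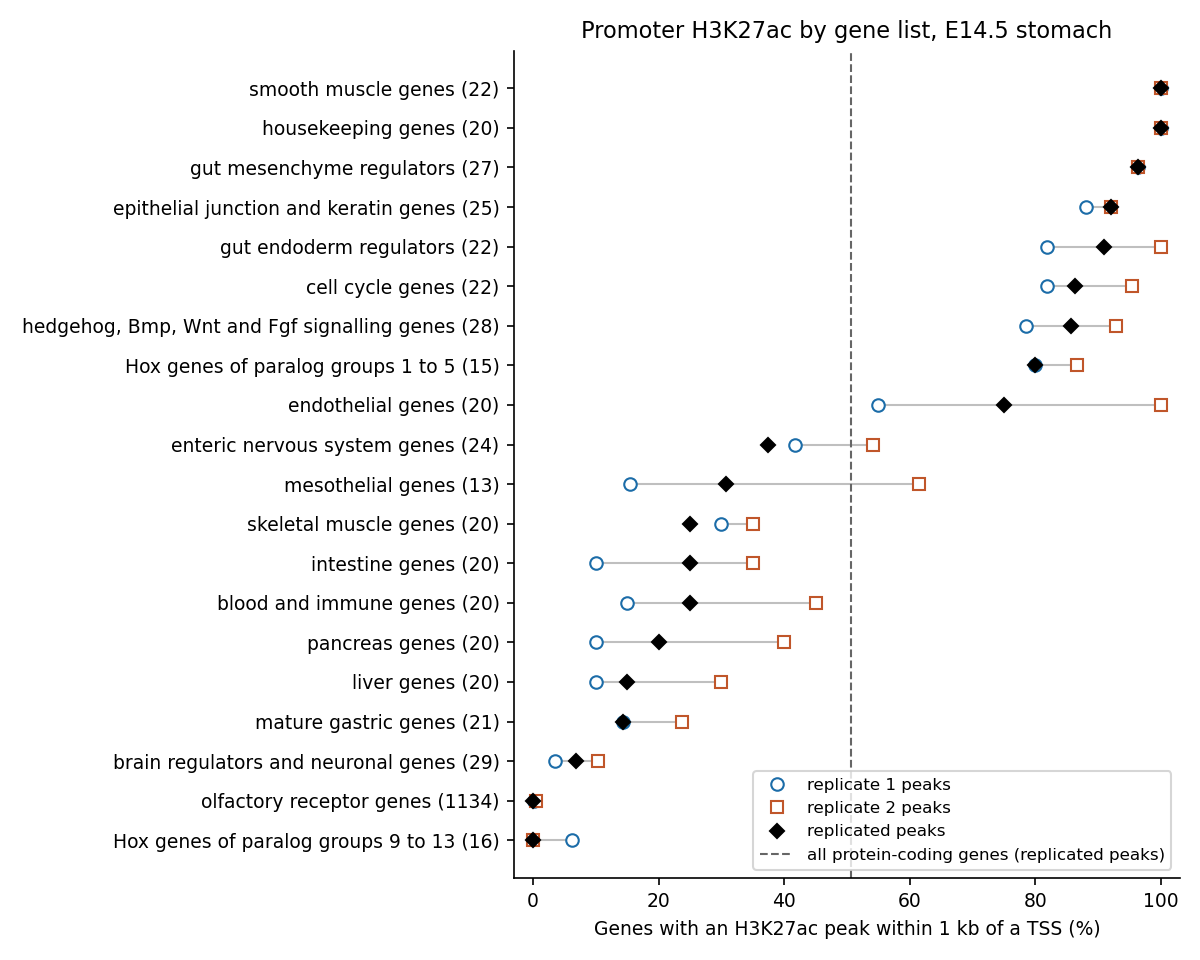
Share of each list's genes with an H3K27ac peak within 1 kb of a TSS, in percent on the horizontal axis, for 20 lists with the number of genes in brackets. Circles are replicate 1, squares replicate 2, joined by a grey line, diamonds the replicated set, and the dashed line all protein-coding genes at 50.7%; smooth muscle and housekeeping genes lie at 100% in every peak set, and endothelial genes spread from 55.0% to 100%.

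Hox genes differed by their place in the clusters. Genes of paralog groups 1 to 5, which lie at the 3′ end of each cluster and are used in anterior regions, had a promoter peak at 12 of 15 (Fisher's exact test, adjusted p = 0.0416). Genes of groups 9 to 13, used in posterior regions, had 0 of 16 (adjusted p = 4.02e-05, Fisher's exact test). In a comparison added after these counts were seen, the lists differed from each other (Fisher's exact test, p = 3.22e-06), also in replicate 1 (12 against 1 gene, p = 3.85e-05) and in replicate 2 (13 against 0, p = 5.09e-07, Fisher's exact test for both). A peak of 49062 bp (11:96298459–96347520) covered the promoters of Hoxb3, Hoxb4 and Hoxb5 with an enrichment of 31.6, next to that of Hoxb2 at 32.4 (11:96347729–96353874). A peak of 23542 bp (6:52162502–52186043) covered those of Hoxa2 and Hoxa3 at 29.8. The tests of Hox genes counted each gene separately, although such genes share a peak. Hoxb1 (with a peak in replicate 2), Hoxd1 and Hoxd4 lacked a replicated peak among the anterior genes, as did Hoxa9 and Hoxa10 among the posterior ones. The excess of groups 1 to 5 was lost with stricter peaks (73.3%, adjusted p = 0.0741, Fisher's exact test), with pooled peaks (80%, adjusted p = 0.0847, Fisher's exact test) and against CpG-matched lists, which averaged 61.9% (permutation adjusted p = 0.259).

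**Figure D2:**
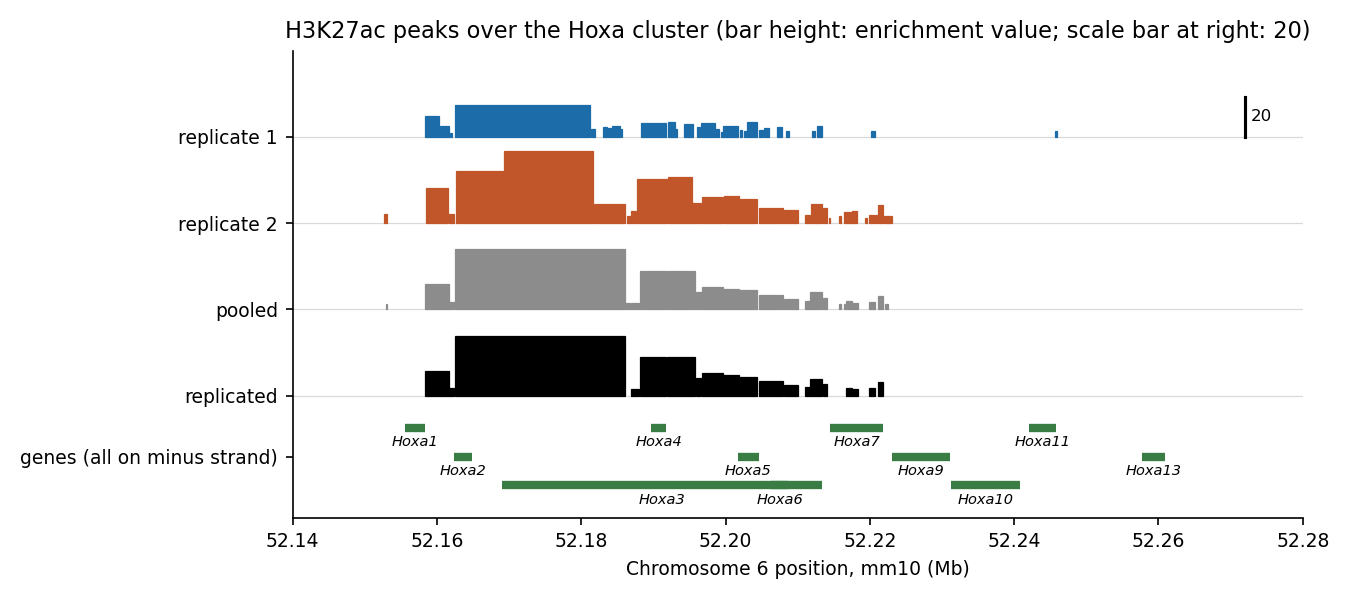
Map of H3K27ac peaks over the Hoxa cluster on chromosome 6 (mm10 position in Mb, horizontal axis), with a track each for replicate 1, replicate 2, pooled and replicated peaks. Bars span each peak and their height is its enrichment value, to the scale bar of 20; green bars are the Hoxa genes, and a replicated peak lies at the promoters of Hoxa1 to Hoxa7 and at none of the 4 genes of groups 9 to 13.

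The strongest promoter peak of the genome, 5:123133574–123144044 with an enrichment of 57.3, was shared by Setd1b, a histone H3 methyltransferase gene, and Rhof, a Rho GTPase gene. It was followed by Sp3, a zinc finger factor (2:72978393–72981729, 56.1), Arid1a, a subunit of a chromatin remodelling complex (4:133750917–133757936, 53.1), Bicral (17:46855386–46859369, 52.5), Zc3h4 (7:16398727–16403997, 51.6) and the histone methyltransferase gene Kmt5b (19:3767143–3769347, 50.9). Next came Tnrc18 (5:142812555–142824542, 50.7), Klf7 (1:64120461–64122821, 50.3), Nfib (4:82503703–82510394, 48.1) and Kansl1 (11:104440558–104443401, 47.1). The first place holds for pooled and replicate 2 values: in replicate 1 the enrichment was 17.5 at Setd1b and 4.998 at Rhof, against 21.8 to 33.1 for the other genes named here, and the summit lay 3254 and 6247 bp from their TSSs. No test was made of this ranking.

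Away from promoters, genes of the mesenchyme, smooth muscle, endoderm, signalling and epithelial lists had more acetylated regions than random lists. Mesenchyme regulators had a median of 6 distal peaks as their nearest gene within 100 kb. The medians were 4.5 for smooth muscle genes, 4 for endoderm regulators, 4 for signalling genes and 2 for junction and keratin genes. Each exceeded random lists matched on the spacing of TSSs, whose median was 0 (permutation test, adjusted p = 0.0008 for each, at the smallest possible unadjusted p). A distal peak lay at 24 of 27 mesenchyme regulators, 20 of 22 smooth muscle genes and 18 of 22 endoderm regulators. The counts were 23 of 28 for signalling genes and 17 of 25 for junction and keratin genes. Only some of the genes named above are given here: Meis1 had 13 distal peaks, Nr2f2 14, Nr2f1 10, Tpm1 17, Smtn 9 and Grhl2 12. Trp63 had 9, although it had no promoter peak in the replicated set. Chosen after their values were seen, Mylk, encoding myosin light chain kinase, and the Fgf receptor gene Fgfr2 had 30 each, Gata4 21, Foxa2 20 and Foxf1 19. These counts moved with the replicate: from replicate 1 and replicate 2 alone, Mylk had 15 and 54, Fgfr2 19 and 78, Gata4 30 and 42, Foxa2 19 and 37 and Foxf1 21 and 33. From replicate 2 alone Meis1 had 32, Grhl2 28, Tpm1 24, Nr2f2 23, Trp63 19, Smtn 16 and Nr2f1 14. Hox genes of groups 1 to 5 had a median of 1 (permutation adjusted p = 0.02). Housekeeping genes, all with promoter peaks, had 0.5 (permutation adjusted p = 0.0606) and endothelial genes 1 (permutation adjusted p = 0.581); the medians were 1 for mesothelial genes, 0.5 for enteric genes and 0 for the other lists, none of which passed. From replicate 2 alone the medians were 14 for mesenchyme, 7.5 for smooth muscle, 10.5 for endoderm, 8 for signalling, 5 for junction and keratin and 2 for anterior Hox genes, and from replicate 1 alone 9, 5, 5, 3, 1 and 2. From replicate 1 alone the junction and keratin median was 1 and no longer passed (permutation adjusted p = 0.136). From replicate 2 alone the endothelial median was 7.5, against 1 in matched random lists, and passed (permutation adjusted p = 0.00333). Medians that did not pass also moved: from replicate 2 alone they were 3 for enteric, 2 for mesothelial and 1.5 for housekeeping genes. Matched random lists then had 1, 1 and 0. From replicate 1 alone the enteric, mesothelial and housekeeping medians were 1, 0 and 0.5, and those of matched lists were all 0. Gastric, pancreas and skeletal muscle genes had a median of 1 from replicate 2 alone, against 0, 1 and 0.5 in matched lists.

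Distal peaks also lay in clusters. Stitching neighbouring peaks among the 31709 distal ones gave 14115 domains, of which 554 (3.92%) lay past the point where the scaled rank curve reaches a slope of 1 and held 37.4% of the summed width times enrichment. The highest was a 137 kb domain of 37 peaks (2:30588538–30725895), 32 of them between genes and 5 in introns, with Cstad as the nearest gene. The domain at rank 2 (6:52158402–52220722) had 11 peaks across Hoxa2 to Hoxa7, 9 in introns. The domain at rank 3 (12:79703811–79950458) had 67 peaks in and beside Rad51b, 31 in introns, with the TSS of Zfp36l1 nearest at 285859 bp from its centre. The next had 3 peaks at Setd1b (5:123133574–123150235), and the domain after it 15 peaks across the noncoding genes Carmn, Mir143 and Mir145a (18:61632068–61694925), whose microRNAs act in smooth muscle, with Il17b nearest. Others held 27 peaks between genes by Ptma (1:86433203–86532392), 19 at Rara, the retinoic acid receptor gene (11:98890783–98971442, 15 in introns), 31 around H19 and Mrpl23 (7:142478584–142579263, 22 between genes), 28 in and by Ddc (11:11820461–11908253, 24 in introns) and 26 in introns of Dnm3, a gene that overlaps Mir199a-2 and Mir214 (1:162135398–162226269). The genes nearest to ranks 11 to 20 were Ski, Parva, Smg6, Meis1, Dlk1, Mrps23, Zfp503, Scyl1, Zfp36l1 and Chd2. Broad promoter peaks whose summit lies over 1 kb from a TSS count as distal here: with only peaks wholly outside the TSS windows, an alternative added after seeing the data, the Hoxa domain ranked 281, the Setd1b domain 7823 and the Zfp503 domain 561. By width alone the Setd1b domain ranked 188 and the Zfp503 domain 159, and from replicate 1 alone the Hoxa domain ranked 85. The Cstad domain was first only in the main ranking and with peaks wholly outside the TSS windows, and ranked from 2 to 5 in the other settings. Counts moved as well: from replicate 2 alone, 86751 distal peaks gave 25242 domains.

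**Figure D3:**
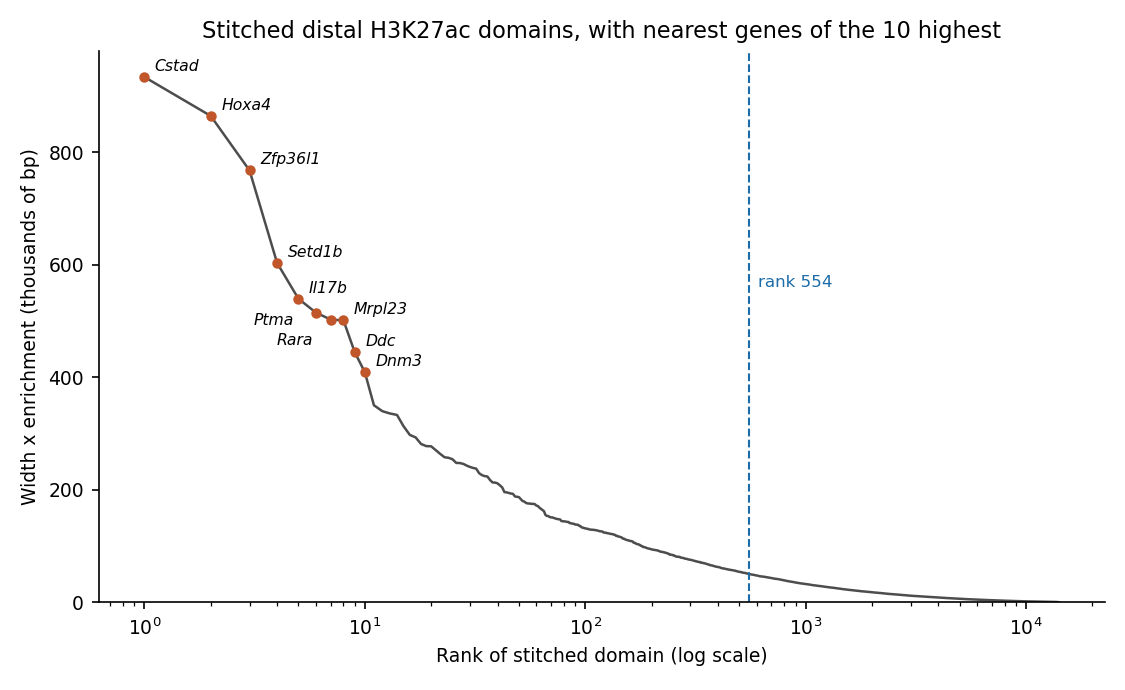
Summed width times enrichment of each stitched distal domain, in bp on the vertical axis (axis labels give units of 1000 bp), against its rank on a log scale. Points are the 10 highest domains, named by the nearest gene, and the dashed line is rank 554; the highest reaches 933447 bp.

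The replicates were also compared for genes of another tissue carried along in 1 pool. At 47584 peaks each, 579 genes had a promoter peak in replicate 1 only and 1363 in replicate 2 only. Of 20 lists 0 passed (Fisher's exact test, adjusted) and 0 had an unadjusted p under 0.05, the smallest being 0.0888 for skeletal muscle genes. With all peaks the counts were 221 and 2548 genes, again with 0 lists past the threshold and 1 with an unadjusted p of 0.0294 (Fisher's exact test). No list had more than 7 genes in either class at equal numbers of peaks, or more than 9 with all peaks, so an excess in replicate 2 could not have passed: with all of a list's genes on that side the smallest possible p was 0.111 and 1 (Fisher's exact test, unadjusted). The comparison therefore leaves open whether the lists differ.

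The last comparison was of transcription factor consensus sequences in distal peaks and in GC-matched neighbouring windows. The forkhead (FOX) sequence was in 8.08% of 31704 distal windows against 5.28% of neighbours, a ratio of 1.53 (Fisher's exact test, adjusted p = 9.94e-45). The TEAD sequence, bound by the Hippo pathway's factors, had 15.2% against 11.3% (ratio 1.35, adjusted p = 1.08e-47), and the CArG box, bound by Srf, 0.880% against 0.536% (1.64, adjusted p = 8.28e-07, Fisher's exact test for both). The SOX sequence had 13.03% against 10.1% (1.29, adjusted p = 2.74e-30, Fisher's exact test), but the same letters written backwards also gave 1.29. Backwards sequences gave 1.104 for FOX, 0.980 for TEAD, 1.36 for CArG and 1.08 for AP-1, of which FOX, CArG and AP-1 passed. Excesses also passed for AP-1 (1.14), HOX-PBX (1.11), KLF (1.13, against 1.48 backwards), HNF4 (1.25) and ETS (2.15, the highest ratio that passed, in 73 windows). GATA (1.05), NKX (1.057), GLI (1.01), HNF1 (2.43, in 17 windows), CTCF (0.987) and NR2F (0.75, in 6 windows) did not pass. From each replicate alone GATA, NKX and HNF1 passed as more frequent (Fisher's exact test, adjusted p from 0.000217 to 0.0295), as did GLI from replicate 1 alone (Fisher's exact test, adjusted p = 0.00498). CTCF passed as less frequent in 300 bp windows and from replicate 2 alone (Fisher's exact test, adjusted p = 0.00187 and 0.0441). In 300 bp windows the CArG, AP-1, HOX-PBX and ETS calls were lost and KLF turned to 0.833. The ETS call was also lost with stricter peaks, among peaks overlapping both replicates and from each replicate alone (Fisher's exact test, adjusted p from 0.0601 to 0.345). The HOX-PBX call was also lost with stricter peaks (Fisher's exact test, adjusted p = 0.792), and without GC matching its ratio turned to 0.814. In repeat-poor windows the HNF4 and HOX-PBX calls were lost (Fisher's exact test, adjusted p = 0.193 for both). Neighbouring windows held more repeat-masked sequence, 24.5% against 13.02%. In repeat-poor windows the ratios were smaller but still passed for FOX (1.41), TEAD (1.24), SOX (1.22) and CArG (1.47). The FOX ratio was 1.35 in 300 bp windows and 1.23 without GC matching, and passed in both.

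**Figure D4:**
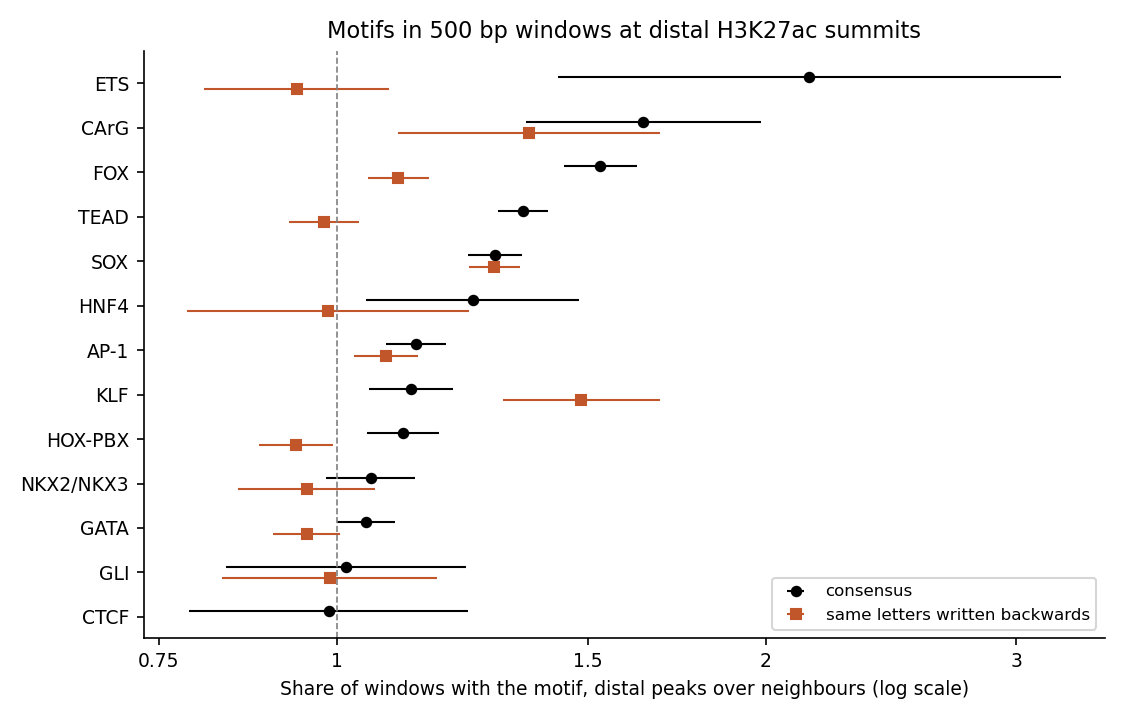
Ratio of the share of distal windows to the share of neighbouring windows with each consensus, on a log scale, with 95% intervals that cover counting error only. Circles are the consensus and squares the same letters written backwards, and motifs found in under 100 windows are left out; FOX and TEAD lie above their backwards sequences, and SOX lies at 1.29 with either.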

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

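Both tests of why replicate 2 has more peaks were chosen only after the result was seen. Peaks on contigs outside the placed chromosomes were left out of every comparison, and some were present: 6 in replicate 1 and 10 in replicate 2, on 5 contigs in each, with enrichment values up to 24.6 and 34.3. They are given because they lie in data that the comparisons leave out, and no test was made of them.

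Replicate 2 had 2.24 times the peaks of replicate 1. If weaker peaks passing a p threshold in 1 library made the difference, the numbers of strong peaks could be alike. Peaks with a −log10 q-value of 5 or more numbered 11508 in replicate 1 and 36073 in replicate 2, a ratio of 3.13 (counting interval 3.07 to 3.20). This decides nothing, because q-values, like p-values, depend on depth, and the depths are unknown. The 58859 peaks of replicate 2 beyond the count of replicate 1, ranked by p, had a median enrichment of 3.17 and a median width of 241 bp, and 8.76% overlapped a replicate 1 peak; that ranking selects weak peaks, so these values decide nothing either. A deeper library, the second control file used for replicate 2 or a better enrichment could each give more peaks of either kind, and the lists hold no depth to separate them. If other tissue in 1 pool made it, genes of the liver, pancreas and intestine would have more promoter peaks in replicate 2 at equal numbers of peaks; their mean share was 10 percentage points higher, and the share over all genes was also higher, 50.4% against 46.9%. The lists hold too few genes for a test of this excess to pass, so it stays open. No biological explanation was tested, since the design has 1 group.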

How the results depend on the processing

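The settings with peaks overlapping both replicates, whole peaks outside the TSS windows, repeat-poor windows and backwards sequences were chosen only after the result was seen; the other settings were planned. Overlap of the replicates, the TSS and intergenic shares and the counts of domains (447 to 756) kept their direction and side of the threshold, or stayed within 1.5 times, in every setting run, although the TSS share over random placement ran from 5.85 with the 2.5 kb window and 6.98 without replicate 1 to 14.2 with peaks overlapping both replicates. Direction and side of the threshold were also kept by the promoter calls for mesenchyme, smooth muscle, endoderm, epithelial, signalling, housekeeping, brain, posterior Hox and olfactory genes and the distal calls for mesenchyme, smooth muscle, endoderm, signalling and anterior Hox genes. For all the changes given here the cause was not tested, apart from backwards sequences, which are another search. No paired analysis was possible because the design has 1 group. Depth is unknown, which limits what a missing peak can show.

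With a 50% overlap, 36.9% of replicate 1 peaks were in the replicated set, 38.5% of that set overlapped replicate 1 and 34.8% both, and rho was 0.790. With stricter peaks, 95.1% of pooled and 81.8% of replicate 2 peaks were in it, 31.8% of it overlapped replicate 1 and 31.3% both, and rho was 0.626; rho was 0.586 from −log10 p-values and 0.527 with equal numbers of peaks. Exons held 2.05% with the 2.5 kb window, 2.20% with stricter peaks and 2.22% with peaks overlapping both replicates, and introns 33.9%, 32.8% and 32.4%. From each replicate alone, exons held 2.83% to 3.07% and introns 37.1% to 45.0%.

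Among promoter lists, calls were lost for endothelial genes, which had 75% with the 2.5 kb window, 60% with stricter peaks, 50% with equal numbers of peaks and 45% with peaks overlapping both replicates. They were also lost for skeletal muscle genes, with 30.0% in the 2.5 kb window and 25% with peaks overlapping both replicates, and for anterior Hox genes, with 73.3% with stricter peaks; with these mesothelial genes had 7.69% and passed. Calls were lost against CpG-matched lists, which averaged 24.3% for gastric, 21.8% for blood, 27.2% for liver, 38.5% for pancreas, 23.4% for intestine, 36.5% for skeletal muscle, 77.8% for cell cycle and 61.9% for anterior Hox genes. From each replicate alone the shares ran from 55.0% to 100% for endothelial, 15.0% to 45.0% for blood, 15.4% to 61.5% for mesothelial, 10% to 40% for pancreas, 10% to 35% for intestine and 30.0% to 35.0% for skeletal muscle genes. Calls were lost without replicate 1 for blood, pancreas, intestine and skeletal muscle genes, and without replicate 2 for endothelial and skeletal muscle genes. From each replicate alone, distal medians ran from 1 to 5 for epithelial genes, with the call lost without replicate 2, and from 2 to 7.5 for endothelial genes, which passed without replicate 1; in the other settings these had medians of 0.5 to 1. Matched random lists had single-replicate medians of 0 for epithelial genes and 0 to 1 for endothelial genes. Housekeeping genes passed at 0.5 with whole peaks outside the TSS windows.

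Motif ratios in 300 bp windows were 1.02 for AP-1, 1.37 for CArG, 1.05 for HOX-PBX, 1.29 for NR2F (4 windows against 3), 0.536 for CTCF, 0.833 for KLF and 1.54 for ETS. With stricter peaks they were 10.3 for HNF1, 0.930 for GLI, 1.01 for HOX-PBX, 1.43 for NR2F and 1.68 for ETS. The HNF1 ratio rests on 12 of 20177 windows against 1 of 17263 neighbours, and that of NR2F on 5 against 3. Neither gives a reliable size. Without GC matching the ratios were 0.891 for GATA, 1.47 for GLI, 0.814 for HOX-PBX, 3 for NR2F (6 windows against 2), 1.21 for CTCF and 0.962 for NKX. KLF then had 1.79, against 1.13 with matching. In repeat-poor windows the ratios were 1.17 for HNF4, 1.055 for HOX-PBX and 2.29 for NR2F (5 windows against 2), and with peaks overlapping both replicates 1.32 for ETS. From each replicate alone they ran from 1.03 to 1.09 for GATA, 2.88 to 4.33 for HNF1, 1.03 to 1.40 for GLI, 0.832 to 0.856 for CTCF, 1.24 to 1.43 for ETS and 1.08 to 1.09 for NKX. For HNF1 these were 49 windows against 17 from replicate 2 and 13 against 3 from replicate 1. Calls were lost for AP-1, CArG, HOX-PBX and ETS in 300 bp windows, for HOX-PBX and ETS with stricter peaks, for HNF4 and HOX-PBX in repeat-poor windows, and for ETS with peaks overlapping both replicates and from each replicate alone. Calls were gained for GATA, HNF1 and NKX from each replicate alone, for HNF1 with stricter peaks, for GLI without replicate 2 and without GC matching, and for a lower share of CTCF in 300 bp windows and without replicate 1; GATA passed as less frequent without GC matching. Backwards sequences gave 0.953 for GATA, 0.857 for HNF1, 0.986 for HNF4, 0.980 for TEAD, 0.988 for GLI, 0.936 for HOX-PBX, 3 for NR2F (3 windows against 1) and CTCF (6 against 2), 0.937 for ETS and 0.952 for NKX.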

Other observations

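The tests of genes near clustered domains, of mesenchyme against endoderm promoters and of pooled promoter peaks were chosen only after the result was seen. The 554 domains past the slope of 1 had 499 genes as their nearest. Among these were 9 of 27 mesenchyme regulators, such as Foxf1, Meis1, Nr2f2 and Tcf21, and 7 of 22 endoderm regulators, such as Foxa1, Foxa2, Gata4, Shh and Sox2 (Fisher's exact test, adjusted p = 5.11e-08 and 2.62e-06). They also held 7 of 28 signalling genes, 4 of 25 junction and keratin genes and 3 of 22 smooth muscle genes (Fisher's exact test, adjusted p = 1.21e-05, 0.00929 and 0.044), while 0 of 1134 olfactory receptor genes were among them. The domains are stitched from the same distal peaks that these 5 lists already had in excess, and the genes were not matched on the spacing of TSSs, so these counts are no separate evidence. Ptch1 and Shh stand on the signalling list and on the mesenchyme or endoderm list, so these lists are not independent.

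Promoter peaks of mesenchyme regulators were stronger than those of endoderm regulators, with a median pooled enrichment of 16.3 over 26 genes against 9.76 over 20 genes (two-sided permutation test, 100000 permutations, p = 0.00227). Promoter CpG content, measured at the gene's 5′ end, did not account for the height of the mesenchyme median: the central 95% of CpG-matched lists of genes with a peak reached up to 11.1. The medians of matched lists were 8.06 for mesenchyme and 7.45 for endoderm. The test between these lists was not itself matched on CpG. Anterior Hox genes, with a median of 24.5 over 12 genes, and housekeeping genes, with 13.9 over 20 genes, also lay above their matched lists, and mesothelial genes, with 3.74 over only 4 genes, lay below (permutation adjusted p = 0.0017, 0.0221 and 0.0193). The anterior Hox median counts shared peaks more than once: Hoxb3, Hoxb4 and Hoxb5 share the peak at 31.6, and Hoxa2 and Hoxa3 that at 29.8. The test treated these genes as separate, so its p does not hold for separate peaks. Smooth muscle genes, which are also mesenchymal, had a median of 9.86 (permutation adjusted p = 0.144 against matched lists, whose median was 7.01), and they were not compared with the other lists. The cause stays open, and no biological explanation was tested.

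X-linked genes had a replicated promoter peak less often than autosomal ones, 31.4% of 948 against 52.0% of 20722. The many multi-copy and germ-cell gene families of the X are a candidate explanation. Among genes outside unnamed models and families of 10 or more numbered members, the shares were still 41.3% of 467 and 61.2% of 10792 (Fisher's exact test, adjusted p = 4.09e-17). They were 37.7% against 56.6% in replicate 1 and 50.5% against 68.7% in replicate 2. Large numbered families alone therefore do not account for the difference. Smaller families and single-copy germ-cell genes were not removed, so their part stays open. A lower dosage of the X than of autosomes in these pools of male and female embryos may also matter and was not tested.

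Posterior Hox genes had no replicated promoter peak, and Hox genes of groups 6 to 8 had one at 2 of 2 in Hoxa, 3 of 3 in Hoxb, 1 of 2 in Hoxc and 0 of 1 in Hoxd, counts that were not tested. The values argue against promoter CpG content, measured at the gene's 5′ end, as the cause, since CpG-matched lists had a share of 50% at their 2.5th percentile. No posterior Hox promoter had a pooled peak either, a lower share than in other genes (Fisher's exact test, p = 2.07e-06). Peaks lost between the pooled and the replicated set therefore do not account for the missing peaks. Both lists stop at a −log10 p-value just above 2, so signal under that threshold stays open. A candidate explanation is that posterior Hox promoters are inactive in most cells of the stomach. It was not tested, since the design has 1 group.

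Mature gastric genes had promoter peaks at 3 of 21. Their promoters are poor in CpG, and CpG-matched lists reached down to 9.52% at the 2.5th percentile, below the 14.3% of this list, so CpG content alone may account for the low share. In the pooled list 4 of 21 had a promoter peak, again a lower share than in other genes (Fisher's exact test, p = 0.000724). That list stops at a −log10 p-value just above 2, as the replicated set does, and the test was not matched on CpG. It therefore cannot decide whether peaks just under the threshold account for the low share. A later onset of these genes is open, and no biological explanation was tested.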
